A study of Mus musculus with 34 samples.

How the data were processed

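The series compared adult mice with intact Setdb1 (WT) and mice in which Setdb1, a histone H3 lysine 9 methyltransferase, was removed by a CK-Cre driver (CK-KO). It holds 34 samples, 6 of them input libraries. RNA was taken from prefrontal cortex homogenate of 2 WT and 2 CK-KO animals. Chromatin came from nuclei of cortical neurons sorted with an antibody against NeuN: H3K9me3 and H3K27ac with 3 libraries per genotype, CTCF with 4 per genotype, and in situ Hi-C with 2 per genotype. Groups were taken from the sample titles. The H3K27ac libraries and some inputs are titled KO, and their genotype label is CK-KO, per the labels. The H3K9me3 and CTCF libraries held both sexes, the H3K27ac and Hi-C libraries males, and the RNA libraries females, per the labels.

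TopHat2, HTSeq, limma, FastQC 0.11.2, Bowtie2, SAMtools 0.1.19 and HiC-Pro are named in the submitters' processing notes, with no role given for any, and the build is mm10. For RNA-seq, the authors deposited a limma comparison of CK-KO against WT with a log2 fold change, a mean log2 expression, a t score and p-values per gene, per the file headers. Of that table, 728 genes of chromosome 1 from 3.21 to 87.8 Mb were used here, and no values per library entered. The standard error of each log2 fold change was taken as the fold change divided by t.

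For each ChIP-seq target, the authors deposited a table of changed regions, found with 1 kb windows that each had a window p-value under 0.001. Regions not passing that limit are not listed, so unchanged regions were not used here. Per the file headers, each region carries the normalized read count of every library, a mean signal per group, an enrichment ratio per group, a log2 fold change, and region p-values. The enrichment was read as a ratio over input, although the headers do not say so. The libraries in a cell are unnamed, so neither sex nor animal could be tied to a value. The adjusted p of listed regions reached 1, so a listed region is one that passed the window limit, not one that passed an adjusted threshold. The planned count test needed counts per library, and the tables held normalized values, so the authors' deposited comparison was used as the main result. The normalized counts were whole multiples of 1 step per library in 100% of tested values, within a tolerance of 0.1 of a read. Whole reads were recovered by dividing by that step, and edgeR was run on them as an added alternative.

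For Hi-C, the authors deposited raw counts of contacts between 20 kb bins for each library, per the file headers, with no normalization. The libraries held 133280840 and 81516859 contacts in WT and 127853213 and 99648212 in CK-KO. The depth of the ChIP-seq and RNA-seq libraries outside the listed regions was unknown.

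Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used. The clustered protocadherin (cPcdh) domain was the span of all Pcdha, Pcdhb and Pcdhg genes in an mm10 annotation, rounded outward to 20 kb bins. Regions in the domain were counted against all windows of its length, which overlap each other. Co-location was the share of regions of a mark within 10 kb of a region of another, against 1000 circular shifts within each chromosome, two-sided, where 0.002 is the smallest p the shifts can give. For 20 gene lists, genes within 10 kb of a changed region were counted and compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 120 tests. This comparison was added after seeing the data. It counts every gene of a cluster as independent and takes no account of gene length, so long genes meet more regions. Circular shifts of the regions keep clusters and gene lengths, so the adjusted p against shifts is given beside it for most results. Shifts are mostly the stricter for clustered or long genes, but they compare with random positions and not with other genes. For H3K27ac gains they can be the looser: they expect 105 of 399 zinc finger genes, while 41.6% of other genes lay near a gain. Against shifts, 6 of 120 tests had an adjusted p under 0.05. All 6 had the smallest p that 1000 shifts can give, 0.002, and the adjustment made it 0.04. The next smallest permutation p, 0.004, became 0.0599, so the number of shifts limits how low these values can go. The lists covered clustered and nonclustered protocadherins, zinc finger genes, imprinted, germline, interferon response and MHC class I genes, glutamate and chemosensory receptors, H3K9 methylation machinery, CTCF and cohesin, immediate early genes, and markers of excitatory neurons, interneurons, astrocytes, microglia, oligodendrocytes, endothelial and mural cells, choroid plexus and blood, and striatum.

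Observed over expected Hi-C contacts were contacts at 100 kb or more divided by the mean of all bin pairs of the same chromosome and distance in the same library. Windows of 1.2 Mb in 600 kb steps with a mean of at least 50 contacts, and pairs of 100 kb bins 200 kb to 3 Mb apart with a mean of at least 20, were tested with edgeR's quasi-likelihood test, TMM scaling and a Benjamini-Hochberg adjusted p under 0.05. Both were also run with DESeq2. Coverage of a bin was its contacts scaled to the sum over all bins of the library, and cis CPM are contacts scaled to the cis contacts of the library. With 2 libraries against 2, an exact permutation test cannot give a p under 0.333. Animal numbers in the Hi-C titles fall into a 3-digit and a 4-digit series, each with 1 library per genotype, and this series served as a block or was analysed alone in alternatives.

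The count models were tested on simulated data with 200 changed windows, pairs or regions, and false calls made up 4.31% to 6.78% of calls. Simulated windows, pairs and regions were independent and shared a common dispersion, while the real windows overlap. For ChIP-seq that dispersion came from regions already selected for a difference. The rates of false calls and recovery thus describe the simulation and may differ in the real data. For Hi-C windows, 100% of simulated log2 changes of 1 and of 0.5 were recovered. For Hi-C pairs, 56% of changes of 1 and 10% of changes of 0.5 were recovered. On recovered ChIP-seq reads, 88% of H3K9me3, 100% of H3K27ac and 92% of CTCF changes of 1 were recovered, and 25%, 84% and 18% of changes of 0.5.

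Alternatives were planned before the data were examined, except where the closing section says otherwise. They covered thresholds, minimum folds, autosomes, merging of regions, distances, scaling, filters, window sizes, blocks and leaving out each Hi-C library. Genes and regions were named by a rule fixed at the same time: Setdb1; for RNA the 15 called genes per direction with the lowest adjusted p, without predicted genes (Gm) and Rik names; up to 4 members per list; for each ChIP-seq target and direction the 8 regions with the lowest adjusted p; the Hi-C windows past the threshold, up to 3 per direction, and 5 pairs per direction; and at most 6 members of the cPcdh domain per assay. Adjusted p-values at their lowest value were shared by many regions, and ties went to the larger fold. Names outside this rule were chosen after their values were seen. Most are marked so where they appear, but genes of the densest megabases and the reduced Hi-C window from 148.8 Mb of chromosome 5 are not.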

Results

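Setdb1 itself could be followed in the acetylation and coverage data. In the authors' deposited table, an H3K27ac region inside the gene (chromosome 3, 95340901 to 95342400, mm10) fell by 0.58 on the log2 scale and another (95353001 to 95354000) rose by 0.84. Normalized counts at the first were 140 ± 12.4 (SD, n = 3) in CK-KO and 209 ± 48.9 (SD, n = 3) in WT. Hi-C coverage of the bins over Setdb1 was 1.01 times that of WT, so no loss of DNA was detectable in 20 kb bins. Setdb1 RNA was not analysed here.

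The first question was where neurons of CK-KO mice lose the mark the enzyme deposits. The share of sorted nuclei that had lost Setdb1 was not estimated here. H3K9me3, a mark of silent heterochromatin, was lower in CK-KO at 1552 regions and higher at 509, and none of these lay on the X chromosome. Losses were moderate, with a median log2 fold change of -0.85 in the authors' deposited table, and 71.4% of them were intergenic. A loss with the lowest adjusted p lay just ahead of the Pcdhg genes (chromosome 18, 37654701 to 37659400), where normalized counts were 90.0 ± 5.59 (SD, n = 3) in CK-KO and 174 ± 6.28 (SD, n = 3) in WT. A region near Tfap2c, a developmental transcription factor gene (chromosome 2, 172539301 to 172542200), went from 118 ± 4.16 to 70.6 ± 9.13 (SD, n = 3), and one inside Atp8b3 (chromosome 10, 80519001 to 80520100) from 30.9 ± 1.59 to 8.08 ± 1.84 (SD, n = 3). In the authors' deposited table these 3 losses were -0.95, -0.75 and -1.94 on the log2 scale. The remaining losses by this rule were small: the pericentromere of chromosome 4 (log2 fold change -0.24 in the authors' deposited table) and 4 regions in or beside Sfi1 on chromosome 11 (-0.06 to -0.11 in the authors' deposited table), of which 3 had overlapping groups.

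Gains of H3K9me3 were fewer. In the authors' deposited table, the rises by lowest adjusted p included Hnf4g, a nuclear receptor gene (0.92), an intergenic region on chromosome 15 at 57083201 (1.44), intergenic regions 375 kb from Cps1 (1.08) and 569 kb from Ptchd4 (1.29) and regions with almost no change at Rn45s (0.04) and near Ugt1a10 (0.10). A region from the end of Arsi to the start of Camk2a, overlapping both genes (chromosome 18, 60917201 to 60926300), went from 118 ± 25.5 to 624 ± 58.9 (SD, n = 3), and one at 47646001 of chromosome 6 from 80.3 ± 13.3 to 247 ± 36.9 (SD, n = 3). At both, H3K27ac and CTCF reads rose as well, and Hi-C coverage of the bins was 2.40 and 1.63 times that of WT. Gains were densest on chromosome 6 from 129 to 130 Mb, over Clec genes, and from 131 to 134 Mb, over Klra2, Prb1 and Tas2r genes, with 12 each over olfactory receptor genes from 50 to 51 Mb of chromosome 14 and from 18 to 19 Mb of chromosome 9. In 99.3% of all H3K9me3 regions the CK-KO and WT libraries did not overlap, where chance gives 10%, but the regions had been selected for a difference.

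Chemosensory receptor genes stood out among the H3K9me3 gains. Of 1466 such genes, 105 lay within 10 kb of an H3K9me3 gain (7.16%, against 0.689% of other coding genes; Fisher's exact test, adjusted p = 2.55e-56; adjusted p = 0.04 against circular shifts). Examples were Olfr730, with 32.8 ± 1.07 (SD, n = 3) normalized counts in CK-KO and 14.8 ± 3.72 in WT, and Vmn2r108, with 34.9 ± 2.46 and 17.6 ± 2.51. By Fisher's exact test the same list was short of H3K27ac gains (17 genes) and H3K27ac losses (28 genes) alike, and of CTCF gains (16 genes). It was also short of CTCF losses (8 genes) and H3K9me3 losses (10 genes) by that test, but neither shortage passed against circular shifts. Zinc finger genes, many of them repressors of retroelements, had losses at 20 of 394 genes (Fisher's exact test, adjusted p = 0.0419), such as Zfp810, Zfp81, Zfp423 and Zfp930, but not against circular shifts (adjusted p = 0.568). Losses also lay near 3 of 10 endothelial and mural markers (adjusted p = 0.0142; 0.225 against shifts), Vwf and Pdgfrb among them. Gains lay near 3 of 10 choroid and blood markers (adjusted p = 0.0016; 0.0599 against shifts): Clic6, which also lay near a loss, and the beta globin genes Hbb-bt and Hbb-bs.

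The second question was which regulatory elements changed activity. H3K27ac, a mark of active promoters and enhancers, was higher in CK-KO at 28020 regions and lower at 26371, and gains were the larger changes: 1113 gains and 43 losses reached an absolute log2 fold change of 1 in the authors' deposited table. An element beside Anxa3, which encodes an annexin (chromosome 5, 96846001 to 96847200), went from 2.29 ± 0.614 normalized counts in WT to 144 ± 7.22 in CK-KO (SD, n = 3). Elements near Adgrl2, a synaptic adhesion receptor gene (chromosome 3, 148798501 to 148800200), and near Mtr, methionine synthase (chromosome 13, 12261001 to 12263000), went from 8.31 ± 2.19 to 211 ± 18.9 and from 20.7 ± 4.12 to 295 ± 39.3 (SD, n = 3). An intergenic element at 74439201 of chromosome 13 went from 13.9 ± 6.29 to 303 ± 29.0 (SD, n = 3), and the zinc finger gene Zfp933 rose by 3.69 on the log2 scale in the authors' deposited table. The promoters of Pcdha1, Pcdha8 and Pcdhb18 completed the gains by lowest adjusted p, with log2 fold changes of 3.76, 3.66 and 3.66 in the authors' deposited table.

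The leading losses of H3K27ac were smaller. In the authors' deposited table they lay at Wdr64 (-1.19), Batf3, a transcription factor gene (-1.19), Gli2, an effector of Hedgehog signalling (-1.12), and the promoter of the Wnt ligand gene Wnt7b (-1.02). Others were intergenic, near Olfr64 (-1.23 in the authors' deposited table), Sgpp1 (-1.20), Aig1 (-1.10) and Sh2d4b (-0.95). Batf3 went from 202 ± 9.70 to 88.4 ± 12.9 and Wnt7b from 149 ± 1.84 to 73.4 ± 6.07 normalized counts (SD, n = 3). The WT enrichment was 3.56 near Sgpp1, and from 1.15 (Batf3) to 1.90 (near Olfr64) at the other leading losses. If it is a ratio over input, those others were only weakly enriched in WT, so loss of an active element was not shown there. Only 46548 of the 54391 H3K27ac regions had a deposited adjusted p under 0.1, and edgeR on recovered reads called 34736.

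By gene counts, synaptic glutamate receptor genes were near H3K27ac gains and losses, and markers of excitatory neurons near losses, more often than other genes. Of 26 glutamate receptor genes, 20 lay near an H3K27ac gain (Fisher's exact test, adjusted p = 0.00396; 0.0999 against circular shifts, which expect 14.3) and 19 near a loss (adjusted p = 0.0011; 0.568 against shifts, which expect 15.4). Grin2a, an NMDA receptor subunit gene, held both: 143 ± 11.3 against 192 ± 14.6 at 9885601 of chromosome 16 and 188 ± 12.5 against 140 ± 9.98 at 9732101 (CK-KO against WT, SD, n = 3). Of 14 excitatory neuron markers, 11 lay near a loss (adjusted p = 0.00779; 0.0719 against shifts), among them Rorb, Bcl11b and Cux2, with log2 fold changes between -0.26 and -0.19 in the authors' deposited table. Of these 14 markers, 9 lay near a gain (Fisher's exact test, adjusted p = 0.403, and 0.225 against shifts). Of 394 zinc finger genes, 110 lay near a loss (27.9%, against 34.9% of other genes; Fisher's exact test, adjusted p = 0.026; 1 against shifts). Near a gain lay 176 of these genes (44.7%, against 41.6% of other genes, Fisher's exact test, adjusted p = 0.622). Only the comparison with shifts passed (adjusted p = 0.04), which does not set them apart from other genes.

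By Fisher's exact test, 12 of the 20 lists had no adjusted p under 0.05 for any mark. Among these, genes within 10 kb of an H3K27ac gain numbered 6 of 12 nonclustered protocadherins, 12 of 32 imprinted genes, 9 of 35 germline genes, 9 of 33 interferon response genes and 6 of 20 MHC class I genes. They numbered 13 of 21 genes of the H3K9 methylation machinery, 3 of 11 CTCF and cohesin genes and 8 of 20 immediate early genes. For markers of other cells and tissue they numbered 5 of 13 for interneurons, 4 of 12 for astrocytes, 3 of 14 for oligodendrocytes and 4 of 10 for striatum. For H3K27ac gains, the list of H3K9 methylation machinery had an adjusted p of 0.04 against circular shifts, which expect 5.85 genes. By Fisher's exact test the adjusted p was 0.336 (61.9%, against 41.6% of other genes). The result against shifts thus does not set this list apart from other genes.

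The third question was whether CTCF, which binds DNA and anchors chromatin loops, moved. CTCF was higher in CK-KO at 8519 regions and lower at 491, so gains made up 94.55% of changed regions. An intergenic site at 82004101 of chromosome 10 went from 7.76 ± 3.33 to 45.5 ± 3.02 normalized counts (SD, n = 4). A site in Wasf3, which encodes an actin regulator (chromosome 5, 146405401 to 146407300), went from 15.3 ± 3.40 to 68.3 ± 4.30 (SD, n = 4), and one at Tshz2 (chromosome 2, 170027001 to 170029100) from 29.3 ± 9.09 to 120 ± 12.5 (SD, n = 4). In the authors' deposited table, the other leading gains lay at Pcdha1 (2.12), near Tnxb (2.05), near Fam216b (1.97), near Ndufb4 (1.97) and at Cyp21a1 (1.97). Losses with separated groups were an intergenic site at 40071801 of chromosome 7 (-1.17 in the authors' deposited table), sites near Galnt17 (-0.79) and Stk31 (-0.98), and Jakmip3 (-0.28). The losses at Ercc1 and Ptchd2 and near Prex1 and Ppp6c were -0.15 to -0.04 in the authors' deposited table, with overlapping groups.

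CTCF gains lay near 15 of 26 glutamate receptor genes (Fisher's exact test, adjusted p = 0.0016; 0.679 against circular shifts). A site in Grm7, a metabotropic receptor gene, went from 21.3 ± 9.74 to 68.0 ± 5.88 (SD, n = 4), and one in Grik4 rose by 1.18 on the log2 scale in the authors' deposited table. Among microglia markers, the neighbouring complement genes C1qa, C1qb and C1qc lay near a CTCF loss (3 of 13, adjusted p = 0.00706; 0.0719 against shifts), with 79.0 ± 13.5 against 110 ± 3.89 at C1qc (SD, n = 4), while C1qa and C1qc also lay near a CTCF gain. CTCF gains were most crowded over the protocadherin genes, with 44 regions from 37 to 38 Mb of chromosome 18, and over the distal end of chromosome 5, with 40 regions each from 130 to 131 and from 148 to 149 Mb. In the distal part of chromosome 5, taken as 1300 bins of 20 kb from 125000001 after seeing the gains, there were 524, 5.89 times the number its length predicts.

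The clustered protocadherin genes, which give neurons their cell-surface identity, changed in every chromatin assay. The cPcdh domain (chromosome 18, 36920001 to 37860000) held 17 H3K9me3 losses and no gain, 54 H3K27ac gains and 6 losses, and 53 CTCF gains and no loss. As many H3K9me3 losses were found in 2 of 12776 windows of that length, as many CTCF gains in 1, which was the domain itself, and as many H3K27ac gains in 186 (1.46%). H3K27ac gains lay at the promoters of 36 Pcdh genes and CTCF gains at those of 48. Pcdhb18 acetylation went from 26.1 ± 2.59 to 330 ± 22.2 (SD, n = 3), Pcdhgb4 from 14.5 ± 3.34 to 174 ± 12.3 (SD, n = 3), and CTCF at Pcdha6 from 43.2 ± 8.12 to 113 ± 2.22 (SD, n = 4). The losses of acetylation were small, and 5 of the 6 lay in the Pcdha cluster, as at Pcdhac2 (373 ± 23.8 against 447 ± 19.5, SD, n = 3). As a list, 53 of 57 clustered protocadherins lay within 10 kb of an H3K27ac gain, 51 near a CTCF gain, 35 near an H3K27ac loss and 15 near an H3K9me3 loss (Fisher's exact test, adjusted p = 6.26e-15, 6.71e-25, 0.000847 and 3.05e-10). These genes form 1 locus, and against circular shifts the adjusted p was 0.0872 for H3K27ac gains, 0.0599 for CTCF gains, 0.568 for H3K9me3 losses and 1 for H3K27ac losses.

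**Figure D1:**
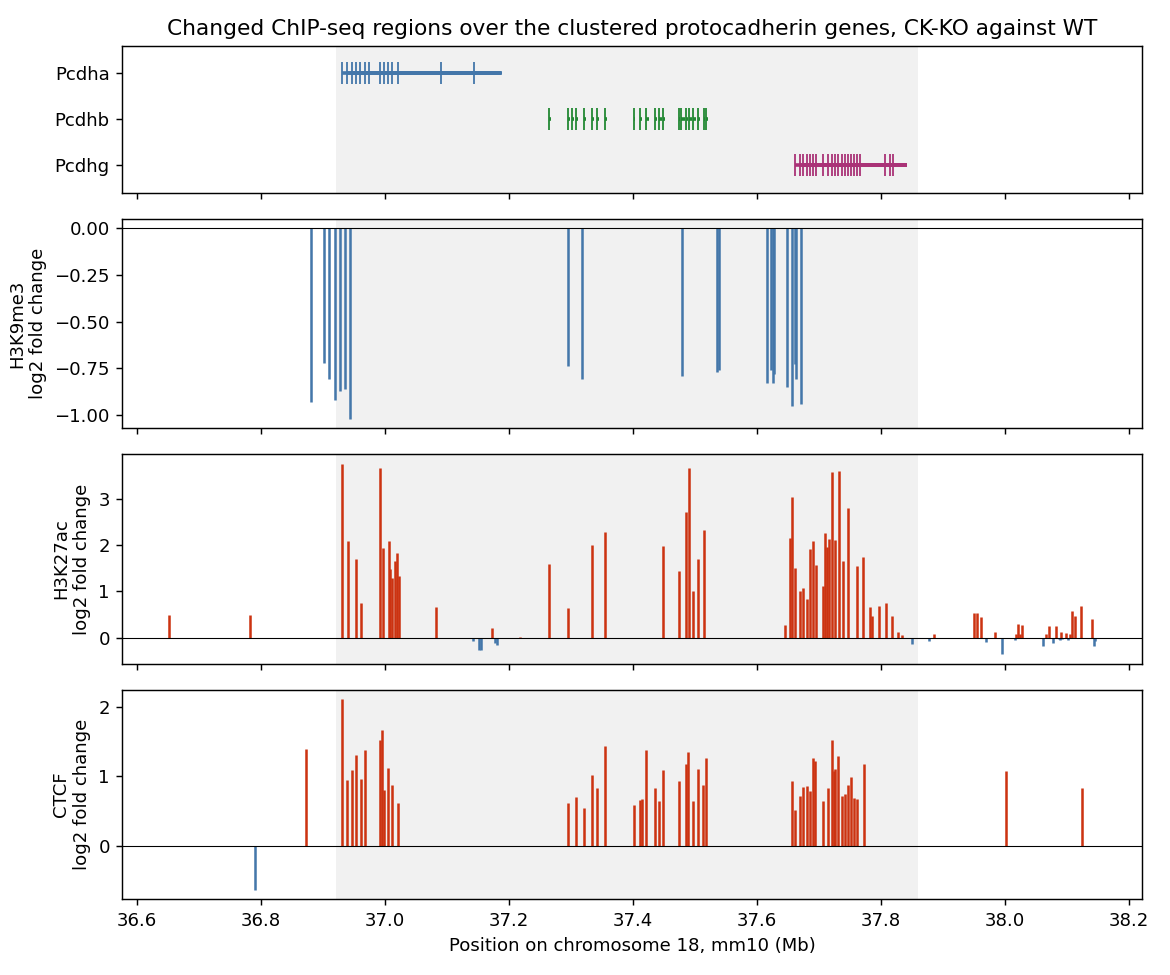
Changed ChIP-seq regions over the clustered protocadherin genes. The horizontal axis is the mm10 position on chromosome 18 in Mb, the top panel shows gene starts and spans, and each vertical line is a changed region with its deposited log2 fold change (red higher, blue lower in CK-KO); the grey band is the cPcdh domain with its 17 H3K9me3 losses, 54 H3K27ac gains and 53 CTCF gains.

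Across the genome, H3K9me3 losses and CTCF gains lay together. Of the losses, 297 of 1552 were within 10 kb of a CTCF gain, 2.50 times the share for circular shifts (permutation p = 0.002, the smallest possible), and 2.42 times without the cPcdh domain. H3K27ac gains lay near fewer losses than shifts gave: 8.96% against 16.7% (permutation p = 0.002). The shortage was larger for H3K27ac losses (4.83% against 16.7%, permutation p = 0.002), and for gains it was absent within 100 kb, at 1.06 times the shifted share (permutation p = 0.22). The few overlaps with large acetylation gains, chosen after their values were seen, included Pdgfrb, a receptor gene of pericytes (chromosome 18, 61080001 to 61082400), which went from 30.9 ± 9.88 to 365 ± 39.8 (SD, n = 3). An intergenic element at 121846901 of chromosome 11 went from 54.2 ± 16.3 to 609 ± 16.5 (SD, n = 3).

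The fourth question was whether chromosome folding changed with these marks. Contacts within the cPcdh domain at 100 kb or more were 1.43 and 1.56 times the expected number in the WT libraries and 1.16 and 1.12 times in CK-KO. The means were 1.49 ± 0.093 and 1.14 ± 0.025 (SD, n = 2), a log2 change of -0.39. An exact permutation test gave p = 0.333, the smallest possible with 2 libraries against 2. The change was the 6th lowest among 11817 overlapping windows. Within the 3-digit series of animal numbers it was -0.30 and within the 4-digit series -0.47. The change was larger between the gene clusters than inside them: Pcdha to Pcdhg contacts went from 1.55 ± 0.019 to 0.71 ± 0.08 of expected, and Pcdhg contacts with the 500 kb ahead of the domain from 1.42 ± 0.026 to 0.558 ± 0.024 (SD, n = 2). The reduction was not limited to contacts of the protocadherin genes. Contacts of the 500 kb ahead of the domain with the 500 kb after it were 1.32 in each WT library and 0.737 and 0.653 in CK-KO, a log2 change of -0.931. Contacts inside the 500 kb ahead of the domain rose, from 0.827 ± 0.0094 to 0.974 ± 0.03 (SD, n = 2). Contacts inside the Pcdha cluster were 1.58 ± 0.083 in WT and 1.67 ± 0.064 in CK-KO (SD, n = 2), with overlapping libraries. Inside the Pcdhb cluster they were 1.52 ± 0.1 and 1.36 ± 0.012 (SD, n = 2).

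**Figure D2:**
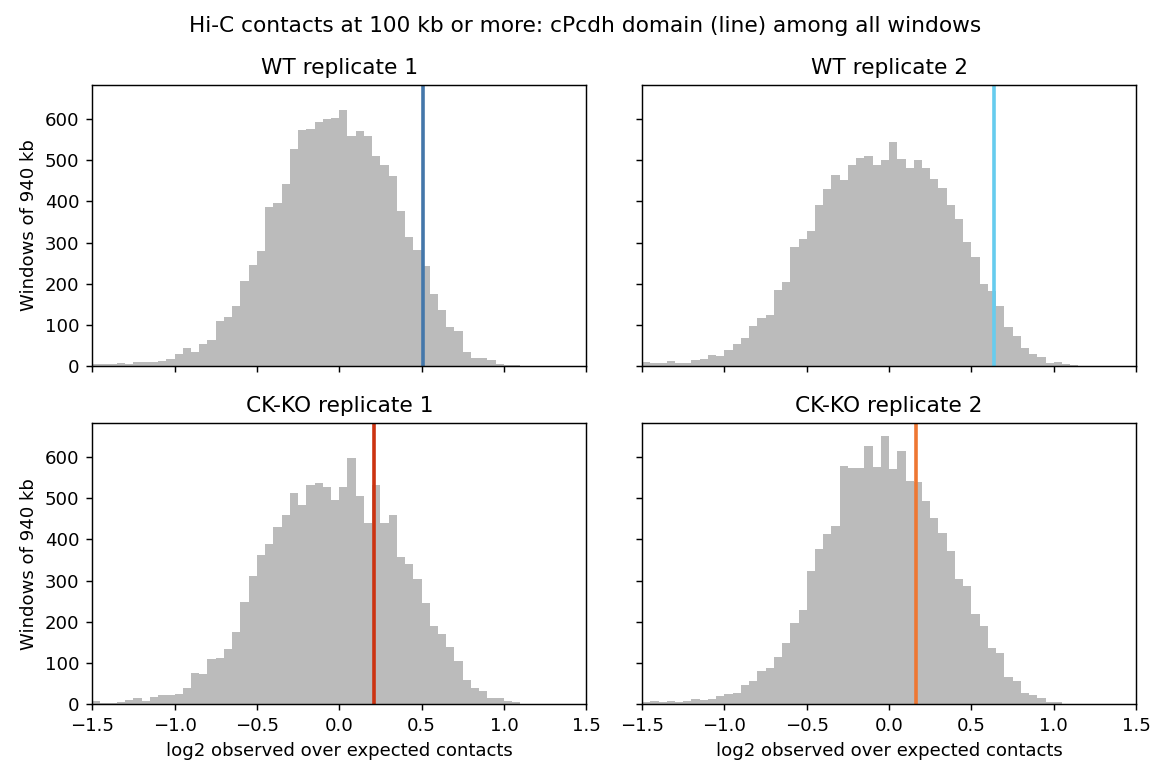
Observed over expected Hi-C contacts of the cPcdh domain in each library. Grey bars count windows of the domain's length by their log2 observed over expected contacts at 100 kb or more, and the coloured line marks the domain, which lay at percentile 93.4 and 96.0 of windows in WT and 71.8 and 69.9 in CK-KO.

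Over the whole genome, edgeR called 1 window of 1.2 Mb higher and 4 lower. The lowest covered the cPcdh genes (chromosome 18, 36.6 to 37.8 Mb; log2 fold change -0.48, edgeR adjusted p = 2.56e-12), with 135 ± 6.1 cis CPM in WT and 97.2 ± 7.2 in CK-KO (SD, n = 2). The others lay on distal chromosome 5: 148.2 to 149.4 Mb with Mtus2 to Medag (-0.34), 125.4 to 126.6 Mb with Dhx37 to Tmem132b (-0.33), and 148.8 to 150.0 Mb with Katnal1 to B3glct (-0.31). The rise at 88.2 to 89.4 Mb of chromosome 7, with Ctsc, Rab38 and Tmem135 (0.27, edgeR adjusted p = 0.021), was not called with the animal-number series as a block (edgeR adjusted p = 0.18). DESeq2 called 23 windows higher and 19 lower. The balance of directions was not stable either: edgeR called 14 higher and 3 lower without WT replicate 2, and 12 and 12 without WT replicate 1.

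Among 339327 pairs of 100 kb bins, edgeR called 1723 higher and 3873 lower in CK-KO, and DESeq2 75 and 350. The reduced pair with the lowest adjusted p joined the bin at 36800001 of chromosome 18, ahead of Pcdha1, with that at 37600001, at the first Pcdhg genes: 2.97 ± 0.28 cis CPM in WT and 0.753 ± 0.037 in CK-KO (SD, n = 2; edgeR adjusted p = 3.25e-34). The next 3 joined the bins at 36800001 or 36900001 to those at 37400001 and 37500001, over Pcdhb genes, with log2 fold changes of -1.64, -1.63 and -1.62. The last of the leading 5 by adjusted p joined Aacs and Tmem132b on chromosome 5 to 126.6 Mb (-1.97). The rise with the lowest adjusted p joined Srebf2, a regulator of cholesterol synthesis, at 82.2 Mb of chromosome 15 to Nfam1 at 83.0 Mb (log2 fold change 1.27, edgeR adjusted p = 1.51e-16). Others lay at 40.7 and 40.9 Mb of chromosome 7 by Vstm2b (0.93), between Camk2b at 5.9 Mb and Ogdh at 6.2 Mb of chromosome 11 (0.87), between the clock gene Cry1 and Btbd11 on chromosome 10 (0.96), and from Mrpl32 at 14.6 Mb to 15.3 Mb of chromosome 13 (1.06). In the cPcdh domain, 25 of 36 tested pairs were lower and 1 higher. In the same distal part of chromosome 5, 382 of 3077 pairs were lower (12.4%, against 0.838% in the rest of that chromosome).

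**Figure D3:**
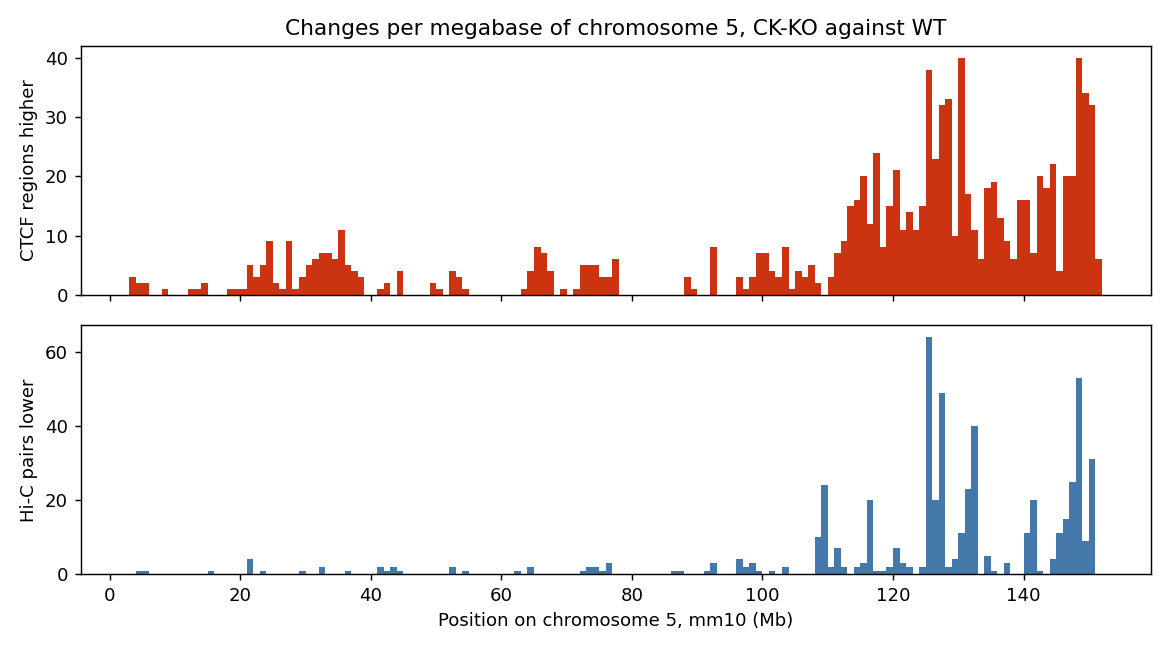
CTCF gains and reduced Hi-C pairs along chromosome 5. Bars give, per Mb of mm10 position, the number of CTCF regions higher in CK-KO (top) and of 100 kb pairs with lower contacts in CK-KO by their first bin (bottom); 524 CTCF gains and 382 lower pairs lay in the distal 1300 bins of 20 kb from 125000001.

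Windows of 1.2 Mb with an H3K9me3 loss had contacts lower by a median log2 difference of -0.0118 than windows without (permutation p = 0.002, the smallest possible). This difference depended on which WT library was used. Without WT replicate 2 it was 0.0335, in the opposite direction, and without WT replicate 1 it was -0.0557. The permutation p weighs only where the losses lie along the genome and takes no account of the spread between libraries. The cis share of contacts was 81.4% ± 1.4 in WT and 81.0% ± 2.0 in CK-KO (SD, n = 2), a difference below the spread between libraries. Cis contacts over 2 Mb made up 26.0% ± 2.5 in WT and 27.9% ± 2.3 in CK-KO (SD, n = 2), with overlapping groups, and were higher in CK-KO by 1.74 and 2.01 points within the 3-digit and 4-digit series. Those under 200 kb made up 44.5% ± 5.9 and 42.9% ± 4.1 (SD, n = 2), with differences of -0.322 and -2.87 points within the series.

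In the part of the RNA table analysed here, 11 of 728 genes had an adjusted p under 0.05 in the authors' limma comparison, 8 higher and 3 lower. The clock transcription factor gene Npas2 fell by 0.93 (SE 0.13), the zinc transporter gene Slc39a10 by 0.52 (SE 0.0656) and Ngef, a guanine nucleotide exchange factor gene, by 0.29 (SE 0.073) on the log2 scale in the authors' deposited table. Scg2, which encodes a secretory granule protein, rose by 0.48 (SE 0.0707), the translation factor gene Eef1b2 by 0.33 (SE 0.0801) and Abca12, a lipid transporter gene, by 1.44 (SE 0.296) in the authors' deposited table. Lgsn, a lens gene, had a log2 fold change of 4.19 (SE 0.725) at a mean log2 expression of -2.62 in the authors' deposited table, so its fold rests on very few reads. The remaining rises included the transcripts RP24-226L19.2 (4.57, SE 0.412) and RP23-259P18.1 (2.34, SE 0.503) in the authors' deposited table, and a Rik gene that overlaps Lgsn. Among members of the fixed lists, Zfp451 (-0.08), Zfp142 (-0.07), Zdbf2 (-0.06) and Kcnj13 (0.01 on the log2 scale in the authors' deposited table) did not pass the limma threshold. None of the 13 genes within 50 kb of an H3K9me3 loss was called by limma, and 2 had an unadjusted p under 0.05. With no called gene near a loss, the direction of calls could not be tested. The median log2 fold change of these genes differed from that of the others by -0.0536 (permutation p = 0.282).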

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

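The tests of copies and of chromatin at Camk2a were chosen after the read counts there were seen, and the tests of where the copies lie were written before the contacts were counted.

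The bin at the start of Camk2a (chromosome 18, 60920001 to 60940000) gave a signal in contacts between chromosomes. Such contacts entered the coverage of bins and the cis share above, but no test of contacts. The bin had 492 and 360 contacts with 42 to 43 Mb of chromosome 6 in CK-KO replicates 1 and 2, and 0 in each WT library. That megabase ranked 1 of 2554 megabases on other chromosomes in both CK-KO libraries.

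Reads upstream of Camk2a were higher in CK-KO for H3K9me3, H3K27ac and CTCF alike. A change of chromatin with no change in copies is argued against: reads divided by the authors' enrichment, which stand for input, rose by 2.29 to 2.63 on the log2 scale, provided that the enrichment is over input. Extra DNA copies met their test, since Hi-C coverage of the bin was at least 2.29 times that of WT in every comparison of libraries. That coverage includes contacts with other chromosomes: 2922 and 1738 in CK-KO replicates 1 and 2, and 587 and 295 in WT. The coverage and the ranks of megabases thus share reads and are not independent. A candidate explanation is a transgene carrying sequence from the start of Camk2a inserted in that megabase of chromosome 6, at rank 1, beside a stretch from 42220001 to 42300000 with Gstk1, Tmem139, Casp2 and Clcn1 where coverage was 0.555 times that of WT. An insertion near 47640001 of chromosome 6, where coverage also rose, cannot be told apart from distance to the first site. The worse of its ranks was 8, in contacts that spread along the chromosome. Both CK-KO Hi-C libraries had the contacts with 42 to 43 Mb and neither WT library had any. Effects of such an insertion thus cannot be told apart from those of removing Setdb1 in the Hi-C comparisons. The same holds for ChIP-seq if the insertion explains the higher reads there.

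CTCF normalized counts at Pcdha1 stood apart in 1 of 4 CK-KO libraries: 199 against at most 169 in the others, a gap of 0.882 of the range. It was the only such case among 46 groups of 4 libraries, and chance gives about 1 in 20.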

How the results depend on the processing

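Alternatives on recovered ChIP-seq reads and the adjusted p under 0.05 for regions were chosen after seeing the data; all others were planned. Of 97 alternatives, 66 kept the side of the threshold, a count within 1.5 times or a value within 1 SD between libraries, 29 moved and 2 reversed. The 66 include edgeR runs on recovered H3K9me3 and CTCF reads, which say little of stability, since those regions had been selected on all libraries. Counts fell with stricter criteria, as stricter criteria must: at an absolute log2 fold change of at least 1 there were 229 H3K9me3, 1156 H3K27ac and 3225 CTCF regions and 6 RNA genes; an adjusted p under 0.01 left 7 RNA genes, and expression at or above the median left 5. edgeR on recovered reads called 34736 H3K27ac regions, and 27058 to 32594 without each library in turn. For Hi-C windows the totals were 42 with DESeq2, 203 for pairs at 400 kb or more, 9 with an offset from expected contacts, 22 in 600 kb windows, and 24 and 17 without WT replicates 1 and 2, 3 and 1 without CK-KO replicates 1 and 2; the window count is thus unstable, while the cause was not tested. For 100 kb pairs the total was 425 with DESeq2 and 2073 to 3360 without a replicate (2287 and 3360 without WT replicates 1 and 2, 2073 and 2101 without CK-KO replicates 1 and 2). The log2 change within the cPcdh domain stayed negative in every alternative: -0.211 at 40 kb or more, -1.09 at 400 kb or more, and -0.483 with the span widened. The 2 reversals were H3K9me3 losses near H3K27ac gains at 100 kb, with 1.06 times the shifted share (permutation p = 0.22), and the contact difference at H3K9me3 losses, 0.0335 without WT replicate 2 and -0.0557 without WT replicate 1; their cause was not tested. Sex as a covariate for CTCF was not run, since libraries are unnamed, and alternatives that need RNA counts per library were not run. With 2 Hi-C libraries per genotype, leaving 1 out assumes that the lone library varies like the others.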

Other observations

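The tests on distal chromosome 5 and on the cPcdh contacts were chosen after the results were seen; those on splits of libraries and on CTCF at Hi-C pairs were written before.

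H3K9me3 losses were crowded at a few loci. Outside the cPcdh and Sfi1 loci, the densest megabases were those of Prox1 on chromosome 1 (12 regions from 190 to 191 Mb), of Tbx3 and Tbx5 on chromosome 5 (12 from 119 to 120 Mb) and of Barhl2 on chromosome 5 (11 from 106 to 107 Mb). H3K27ac gains were densest at 138 to 139 Mb of chromosome 4, with Camk2n1 and Pink1 (103 regions), and at 112 to 113 Mb of chromosome 5 with Sez6l (85). CTCF gains lay near H3K27ac gains more often than shifts gave (37.7% against 16.8%, permutation p = 0.002, the smallest possible) and near H3K27ac losses too (26.9% against 16.9%, p = 0.002 by permutation). H3K9me3 gains lay near few CTCF gains (1.57% against 7.28%, p = 0.002 by permutation). They also lay near few H3K27ac gains (2.36% against 15.9%, p = 0.002 by permutation), so the shortage was not particular to CTCF.

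CTCF gains crowd in the distal part of chromosome 5 from 125000001, a span chosen after seeing them. A change in DNA copies is argued against by Hi-C coverage, with a log2 ratio of 0.00022. H3K27ac regions lay at 2.08 times the genome-wide density in either direction and 2.68 times for gains alone, against 5.89 for CTCF gains. H3K9me3 losses lay at 2.81 times and H3K9me3 gains at 0.186 times that density. The H3K27ac value met the test as worded against a general excess of detectable regions. It does not count detectable CTCF sites, however, so such an excess stays open. Sequence variants carried along in CK-KO mice may create and destroy sites alike. There were 524 gains against 89.0 expected and 21 losses against 5.16. That imbalance would count against such variants as the whole cause only if both are detected equally well, which is not known. Gains made up 94.55% of changed CTCF regions in the whole genome, so the excess of losses (4.07 times, 95% Poisson interval 2.52 to 6.22, counting error only), although it met the test as worded, cannot be set against that of gains, and the explanation stays open. Unchanged CTCF sites were not used here, and no biological explanation was tested.

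Contacts in the cPcdh domain were lower in CK-KO. Uneven coverage of the bins is argued against, since division by coverage gave a log2 change of -0.477. Each series of animal numbers held 1 library per genotype, so a shift shared by a series cancels. The change lay -3.68 SD of all windows from 0 in the nearer series, but that sets single libraries against each other, so an effect that differs between the series stays open. No biological explanation was tested.

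Reduced Hi-C pairs lay over CTCF gains: 60.6% had a gain in either bin, against 40.2% for circular shifts (permutation p = 0.002, the smallest possible). Pairs with higher contacts did so too (65.7% against 39.9%), so the overlap has no direction and may mark regions rich in CTCF sites.

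Splits of the libraries could not weigh chance for the ChIP-seq counts, because the deposited regions had been selected on the real split. On recovered reads the real split gave 2048 H3K9me3 regions and the highest other 1 (1 of 10 splits as large), 34736 and 0 for H3K27ac (1 of 10) and 8970 and 3 for CTCF (1 of 35).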
